A study of Rattus norvegicus with 3 samples.

How the data were processed

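Kidney RNA in 3 libraries, 1 each of the Dahl salt-sensitive (Dahl S), Dahl salt-resistant (Dahl R) and spontaneously hypertensive (SHR) strains, was sequenced after depletion of ribosomal RNA. The number of animals per library is not given in the labels used here. The deposited tables give FPKM (fragments scaled to transcript length and mapped fragments), made by the authors with TopHat 1.3.1 and Cufflinks 1.0.3 per the submitters' processing notes. Each value has a deposited lower and upper confidence limit in FPKM, per the file headers. The confidence level, the genome build, the annotation release, the read totals and the use of strand are not given in the sources used here. All 3 tables hold the same 33194 records in the same order, with 29516 Ensembl gene identifiers and 3678 records marked as long non-coding RNA. Each record has a locus, and 9184 records share theirs with at least 1 other record, so reads of overlapping or antisense genes cannot be separated. Positions are those of the files and bound the locus of a record, with the start counted from 1. The listed span equals that of the locus for 33192 records, so it is not the length of a transcript. Each record was 1 row, and nothing was summed or rescaled in the main analysis.

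The 3 libraries were compared in 3 pairs: Dahl S with Dahl R, Dahl S with SHR, and SHR with Dahl R. Every pair shares a library with each other pair, so the comparisons are not independent of one another. With 1 library per strain no p-value or spread between animals can be had, so a size rule was used. A record was called higher or lower when the log2 ratio of FPKM plus a pseudocount of 1 was at least 1 in size. Records were measured when their mean over the libraries was at least 1 FPKM. In the separate counts of long non-coding records the minimum was 0.5. For each call it was recorded whether the deposited limits of both libraries overlapped. A value listed at 0 with limits of 0 and 0 counts as apart from any lower limit above 0, so for such records this is a weak check. A record stood apart in 1 strain when it was called in the same direction against both others. Similarity is Pearson's r of log2 values over the measured records.

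Depth was compared through the limits. If the distance from value to limit is taken as 2 times the value divided by the square root of a fragment number, that number was whole within 0.01 for 39.5% of low records in Dahl S, 40.6% in Dahl R and 39.1% in SHR. Relative depth was taken from records with whole numbers up to 20. The implied number stopped rising with level, at medians of 36.8 for protein-coding records of 5 to 20 FPKM in Dahl S, 47.0 for 20 to 100 FPKM and 45.5 for 100 to 1000 FPKM. The limits of abundant records therefore hold more than counting error, of a kind not given in the sources used here. The implied numbers served as they are for 100 draws around equal expression, so these draws carry error of the size of the limits. Neither holds the variation between animals.

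Before the data were examined, 38 gene lists were fixed, covering nephron segments, other cell types, blood-pressure regulation, metabolism, stress, the circadian clock and likely admixtures such as blood and fat. Of their 682 genes, 490 were matched by the name in the file, 21 by its description, 13 by RefSeq protein accession and 13 by UniProt entry name, and 145 were not matched. The RefSeq gene table belongs to another assembly (GRCr8) and was used for names only. It matched 7125 of the 7745 records with a RefSeq accession. Each list with at least 3 measured protein-coding members got the percentile of its median log2 ratio among 10000 random lists of protein-coding records, matched on size and on mean expression in 20 bins. Of 105 pairs of list and comparison, 21 had a percentile of at most 2.5 and 32 of at least 97.5. Genes of a list are expressed together, so these percentiles describe the libraries and are not tests.

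The rule for named genes was also fixed then. For each pair it takes the 12 highest and 12 lowest ratios among records with a gene symbol, a mean of at least 5 FPKM, a span of at least 300 bases and limits apart, without small RNA or mitochondrial records. From each list it takes up to 4 members 2-fold apart, or the most abundant members where none was, and from the long non-coding records 5 in each direction. Genes of known interest for blood pressure and long non-coding RNA were given in any case, except 1 that is not reported here. Members mentioned because their limits were apart, long non-coding records chosen for having a locus of their own, and *Nfil3* as a clock gene were picked after their values were seen.

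On simulated data with known differences and error of this size, 2-fold differences were called in 40% of records for Dahl S with Dahl R, 32% for Dahl S with SHR and 26% for SHR with Dahl R. The pseudocount puts an exact 2-fold difference just under the threshold, so these calls were reached only through the added error. For 4-fold differences the figures were 92%, 90% and 86%. Lists of 20 records shifted by a log2 ratio of 0.6 passed the percentile in 10 of 10 cases for each pair, and unshifted lists in 0, 1 and 0 of 10. These lists held random records with independent error, so the rates do not carry over to genes expressed together. Smaller shifts were not simulated. Alternatives tried were other pseudocounts, other minimum means, 3 other scalings between libraries, leaving out records with a locus span under 300 bases, and requiring limits apart. Short RNA inside a longer locus is not removed by the span rule. Summing records of 1 locus, using long non-coding records alone at their locus, and leaving out red blood cell, adipocyte and clock genes were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The files hold no raw reads, so mapping and counting were not repeated, and no reference genome was used here.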

Results

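RNA sequencing of the kidney was deposited for 3 rat libraries, 1 from each of 3 strains. The strains were the Dahl salt-sensitive rat (Dahl S), which becomes hypertensive on a high-salt diet, the Dahl salt-resistant rat (Dahl R), its selected counterpart, and the spontaneously hypertensive rat (SHR). The animals were weaned at 30 days and then kept on a low-salt diet (0.3%), and the labels give an age of 53 days for Dahl S, 54 days for Dahl R and 55 days for SHR. The growth protocol states a shared day of birth, and the reason for the different ages is not given in the sources used here. The labels used here do not say whether a library holds RNA of 1 animal or of several. Strain, age and animals cannot be separated, and there were no replicates, so no difference was tested against the spread between animals. The RNA had been depleted of ribosomal RNA, and the stated purpose of the series was to identify long non-coding RNAs of the rat. Each library lists FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for the same 33194 records, 29516 with Ensembl gene identifiers and 3678 marked as long non-coding RNA. Values above 0 were listed for 26156 records in Dahl S, 26086 in Dahl R and 26091 in SHR. Read totals are not given in the sources used here. The widths of the deposited confidence limits put the depth of Dahl R at 1.33 times that of Dahl S (interquartile range 1.32 to 1.34 over low records) and that of SHR at 1.68 times (1.64 to 1.72). Among records of at least 5 FPKM, the median distance from a value to its limit was 31.6% in Dahl S, 30.6% in Dahl R and 30.01% in SHR. The limits, given in parentheses after each FPKM, have an unstated confidence level and describe 1 library, not the variation between animals.

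The 3 kidney libraries had closely similar profiles. Across the 17902 records with a mean of at least 1 FPKM, Pearson's r of log2 values across genes was 0.965 for Dahl S with Dahl R, 0.958 for Dahl S with SHR and 0.965 for SHR with Dahl R. Genes are not independent replicates. Uromodulin (*Umod*), the main urinary protein made by the loop of Henle, was among the most abundant transcripts, at 4028 (0–9561) in Dahl S, 4475 (0–17164) in Dahl R and 5783 (5748–5817) in SHR. Mitochondrially encoded genes took 21.9% of all FPKM in Dahl S, 24.8% in Dahl R and 28.1% in SHR, and haemoglobin genes took 1.67%, 0.693% and 0.363%. A difference of at least 2-fold (log2 ratio of at least 1 after adding 1 to each FPKM) was counted as higher or lower. Simulated draws that add error of the size of the deposited limits to equal expression set the reference for these counts. Among 14183 protein-coding records, 279 differed between Dahl S and Dahl R against a mean of 162 from these draws, 421 between Dahl S and SHR against 169.55, and 394 between SHR and Dahl R against 133.

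**Figure D1:**
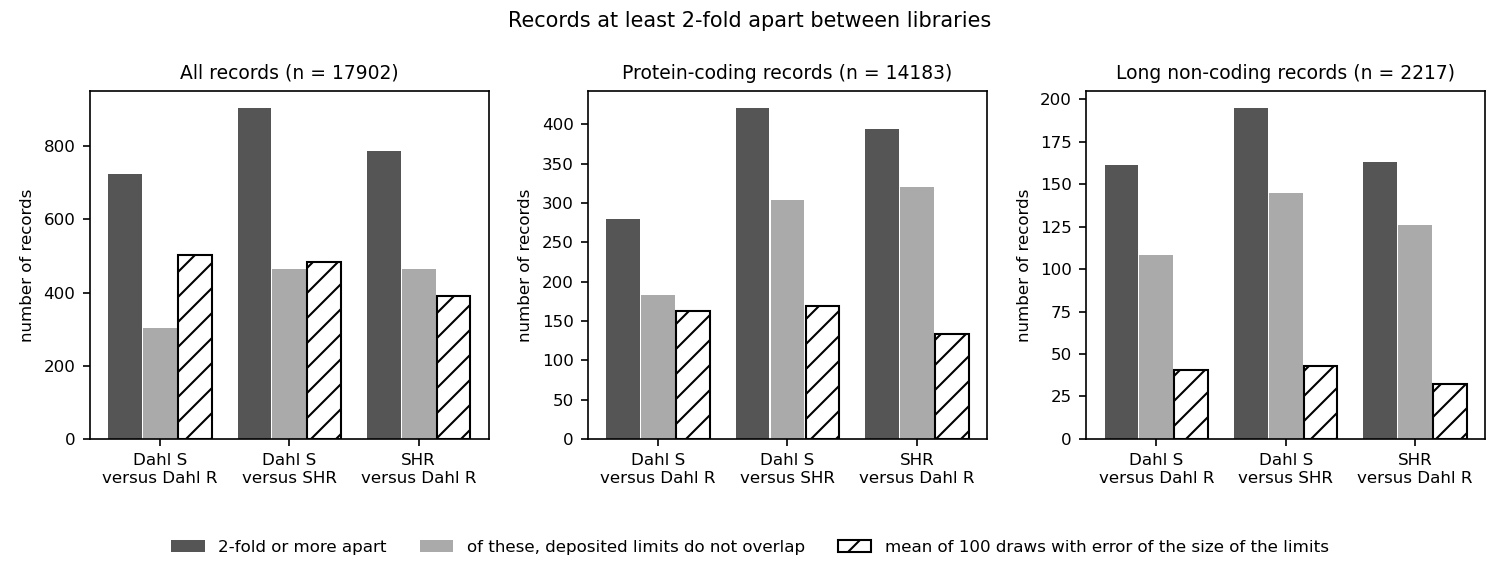
Number of records at least 2-fold apart between libraries (vertical axis) for the 3 comparisons, over all records (n = 17902), protein-coding records (n = 14183) and long non-coding records (n = 2217); dark bars are all such records, light bars those whose deposited limits do not overlap, and hatched bars the mean of 100 simulated draws with error of the size of the limits. Over all records the counts of 723, 905 and 787 stand above the simulated means of 501, 484 and 389.

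In Dahl S compared with Dahl R, the pair that contrasts salt sensitivity with salt resistance, the lists of kidney injury, red blood cell and extracellular matrix genes had medians above 0 in Dahl S, the circadian clock list had a median below 0, and *Pck1* and *Serpinc1* were lower. *Havcr1*, which encodes kidney injury molecule 1 of the tubule surface, stood at 7.64 (5.0–10.3) in Dahl S and 0.653 (0.276–1.03) in Dahl R, and osteopontin (*Spp1*) at 929 (618–1240.5) in Dahl S and 352 (244–460.2) in Dahl R. The clock output transcription factor *Dbp* stood at 41.9 (32.7–51.1) in Dahl S and 140.01 (116–164) in Dahl R, and *Pck1*, the rate-limiting enzyme of gluconeogenesis, at 90.4 (63.3–117) in Dahl S and 324 (194–453) in Dahl R. Antithrombin (*Serpinc1*; ENSRNOG00000002783, chromosome 13, 76548456 to 76575541) stood at 8.18 (5.33–11) in Dahl S and 47.2 (34–60.5) in Dahl R. Of the records named by ratio, the one furthest above Dahl R was *Resp18* (ENSRNOG00000019704, chromosome 9, 74551809 to 74558151), a regulated endocrine protein, at 23.2 (14.9–31.4) in Dahl S and 1.31 (0.438–2.19) in Dahl R.

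By group, 3 of 15 measured kidney injury genes were at least 2-fold higher in Dahl S and none was 2-fold lower, with 12 of 15 above 0 (median log2 ratio 0.62, percentile 100 among random lists of the same size and expression). Beside *Havcr1* and *Spp1* these included fibrinogen alpha (*Fga*), at 4.0 (2.67–5.33) in Dahl S and 0.641 (0.283–0.998) in Dahl R. The injury marker *Lcn2*, at 21.2 (13.9–28.5) in Dahl S and 10.8 (6.85–14.8) in Dahl R, stayed under 2-fold. All 14 fibroblast and extracellular matrix genes were above 0 (median log2 ratio 0.49, percentile 100), and 2 were at least 2-fold higher. *Col1a1* stood at 145 (97.7–192) in Dahl S and 62 (43.2–80.8) in Dahl R and *Lum* at 6.6 (4.09–9.12) in Dahl S and 1.99 (1.05–2.93) in Dahl R. All 10 MHC class II genes (median log2 ratio 0.49, percentile 100) and 10 of 11 macrophage and dendritic cell markers (median log2 ratio 0.31, percentile 99.9) were above 0, and no member was 2-fold apart. Their most abundant members were *Cd74*, the invariant chain, at 395 (306–484) in Dahl S and 282 (218–347) in Dahl R, and *Lyz2*, a lysozyme, at 283 (195–371) in Dahl S and 246 (168–325) in Dahl R. Of 18 immediate early and stress genes, all lay above 0 and 1 was 2-fold higher, *Egr1* at 11 (7.49–14.5) in Dahl S and 4.84 (3.16–6.51) in Dahl R (median log2 ratio 0.45, percentile 100). Adipocyte genes were above 0 in 8 of 9 (median log2 ratio 0.50, percentile 99.99), intercalated cell markers in 10 of 11 (median log2 ratio 0.34, percentile 100) and principal cell markers in 9 of 11 (median log2 ratio 0.18, percentile 98.2), with none 2-fold apart. Red blood cell genes went with these groups, with 4 of 6 at least 2-fold higher in Dahl S (median log2 ratio 1.23, percentile 100). Among them *Hbb* stood at 3089.7 (2419–3760.4) in Dahl S and 1209 (967–1450.5) in Dahl R and, with overlapping limits, *Hba-a2* at 5445 (2579–8311) in Dahl S and 2321 (1283–3359) in Dahl R. Haemoglobin took 1.67% of all FPKM in Dahl S against 0.693% in Dahl R, alongside each list with a median above 0.

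Of 12 measured circadian clock genes, 4 were at least 2-fold lower in Dahl S and none was 2-fold higher (median log2 ratio -0.30, percentile 0). Beside *Dbp* these were *Tef*, at 17.3 (13–21.7) in Dahl S and 52.8 (40.9–64.6) in Dahl R, and *Nr1d1*, at 36 (28.1–43.9) in Dahl S and 95 (70.5–119) in Dahl R. The last was *Per3*, at 4.78 (3.38–6.17) in Dahl S and 11.8 (8.96–14.6) in Dahl R. The activator genes lay on the other side but under the 2-fold rule, *Arntl* at 12.5 (9.95–15.1) in Dahl S and 6.42 (4.66–8.18) in Dahl R and *Npas2* at 8.13 (5.56–10.7) in Dahl S and 3.91 (2.58–5.23) in Dahl R, with limits apart for both. Outside the list, *Nfil3*, a repressor that binds the sites of *Dbp*, was 2-fold higher at 11.9 (7.8–15.9) in Dahl S and 3.75 (2.23–5.26) in Dahl R. Among androgen-dependent and sex-biased kidney genes 3 of 12 were 2-fold lower and 1 was higher (median log2 ratio -0.24, percentile 0.080; -0.16 with a minimum mean of 5 FPKM). The lower ones were *Slc22a2*, an organic cation transporter, at 216 (165–267) in Dahl S and 475 (350.3–599) in Dahl R, *Cyp2d1* and *Cyp2c11*, the last at 0.666 (0.222–1.11) in Dahl S and 5.98 (3.8–8.16) in Dahl R. The higher one was *Akr1b7*, at 2.75 (1.4–4.1) in Dahl S and 0.539 (0.145–0.933) in Dahl R. In the arachidonic acid list (median log2 ratio 0.18, percentile 98.6; 0.12 after median-of-ratios scaling), *Alox15*, a lipoxygenase, was higher at 37.7 (26.7–48.6) in Dahl S and 11.1 (7.56–14.6) in Dahl R, and *Cyp2c11* was the 1 member 2-fold lower. In the oxidative stress and glutathione list, *Gsta2* alone was 2-fold lower, at 215 (151–279) in Dahl S and 523 (340.3–707) in Dahl R (median log2 ratio -0.08, percentile 1.02; -0.13 after upper-quartile scaling). Of 25 proximal tubule markers, *Pck1* was the only one 2-fold apart (median log2 ratio -0.10, percentile 0.51). Reads can be shared between the copies of the Cyp, Gst, Slc22a, Ugt, RT1 and haemoglobin families. Of the list members named in this text, *Aqp4*, *Cd36*, *Cd4*, *Cd74*, *Endog*, *Fga*, *Fgb*, *H19*, *Hba2*, *Hbb*, *Hbb-b1*, *Lipe*, *Nr1d1*, *Plcd1*, *RT1-CE1*, *RT1-O1*, *Scnn1b*, *Slc13a3* and *Sorcs2* share their loci with other records.

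The other records named by ratio were, on the higher side, *Ly6b* at 117 (83.2–151) in Dahl S and 20.4 (13.7–27.2) in Dahl R, the ubiquitin-like modifier *Ubd* at 21.5 (14.2–28.9) in Dahl S and 4.66 (1.91–7.41) in Dahl R, *Crabp1*, *Tnfrsf12a*, *Zmynd15*, *Ankrd61*, *Pppde2* and *Fam76a*. On the lower side they were *Cyp1a1*, a xenobiotic-metabolising P450, at 4.87 (3.05–6.7) in Dahl S and 25.1 (17.8–32.3) in Dahl R, and *Rdh2* at 5.3 (3.48–7.13) in Dahl S and 30.4 (23.3–37.5) in Dahl R. The uroguanylin gene *Guca2b* stood at 1.97 (0.115–3.82) in Dahl S and 12 (7.63–16.3) in Dahl R, and the others were *Bcl6*, *F5*, *Htr2b*, *Ppcdc*, *Pyroxd1* and *Eya3*. *Fam76a* and *Eya3* lie in 1 locus of 14 records and went opposite ways, while the locus sum was 80.5 FPKM in Dahl S and 69.997 in Dahl R. *Zmynd15*, *Ankrd61*, *Pppde2*, *Htr2b*, *Ppcdc* and *Pyroxd1* also share their loci with other records. Over all records 415 were higher and 308 lower in Dahl S, and the deposited limits were apart for 157 and 145 of them. The total of 723 became 1196 with a pseudocount of 0.1, 178 with a pseudocount of 5, 1264 with no minimum, 230 (115 higher and 115 lower) with a minimum mean of 5 and 382 with the records of each locus summed.

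**Figure D2:**
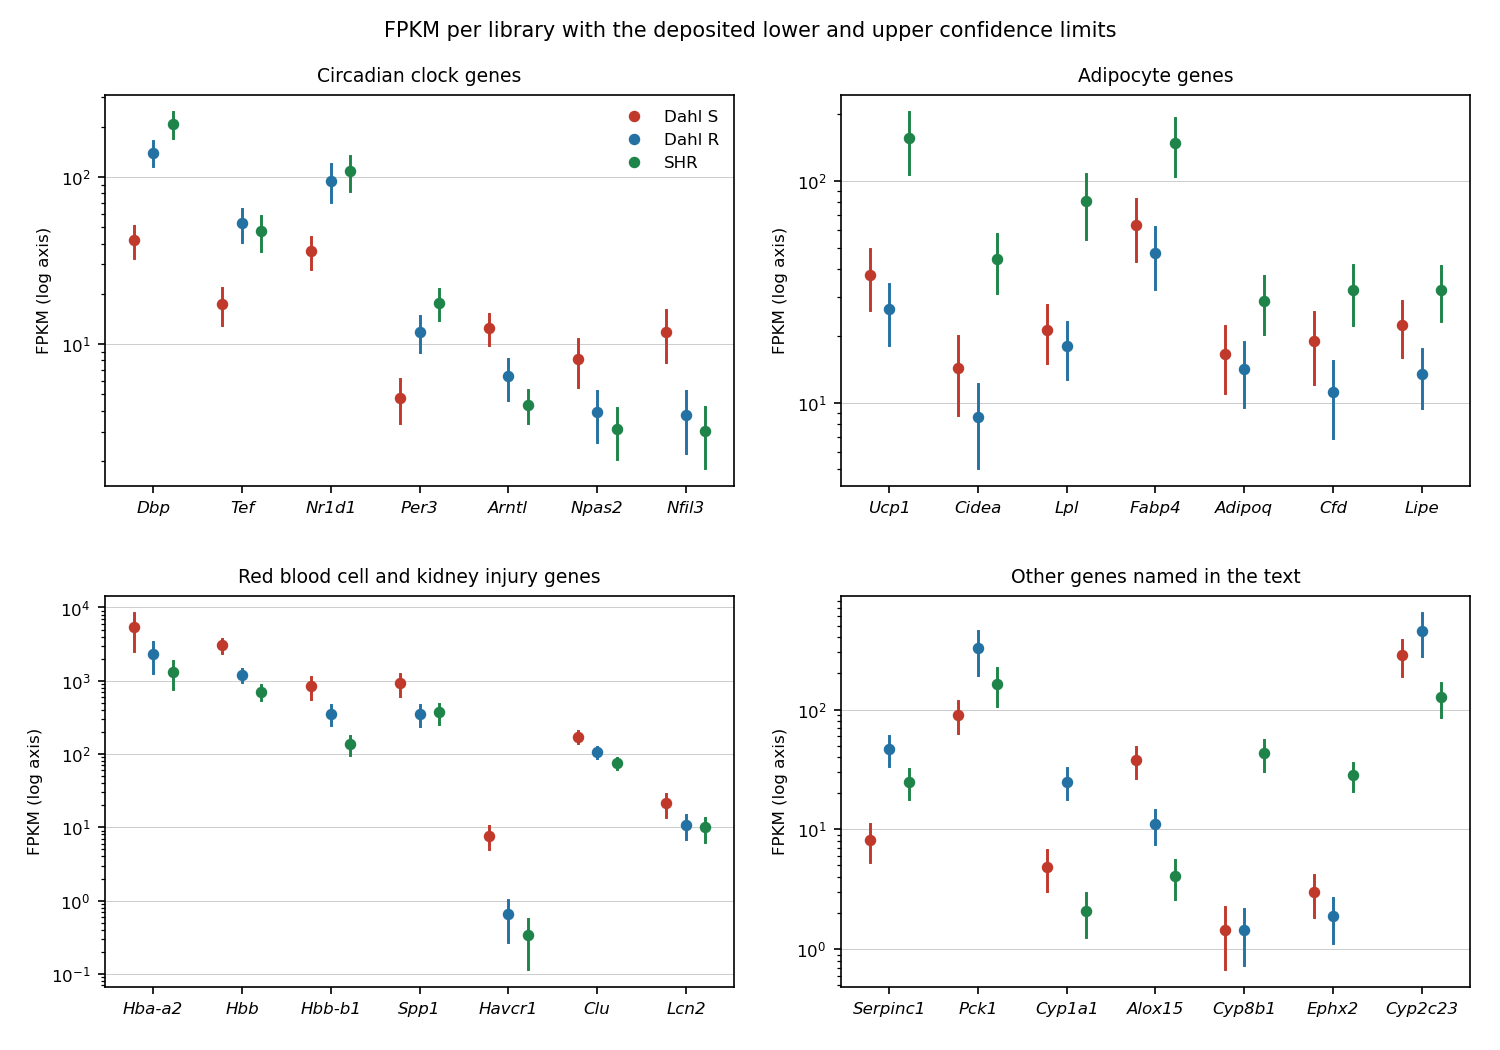
FPKM (log axis) of selected genes in the Dahl S, Dahl R and SHR kidney libraries, with points for the values and lines for the deposited lower and upper limits. Clock output genes such as Dbp are lowest in Dahl S (41.9 against 140.01 and 208), adipocyte genes such as Ucp1 are highest in SHR (155 against 37.7 and 26.3), and Havcr1 is highest in Dahl S (7.64 against 0.653 and 0.34).

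In Dahl S compared with SHR, both of them hypertension-prone strains, the lists of kidney injury, red blood cell, macrophage, lymphocyte and MHC class II genes had medians above 0 in Dahl S, and those of adipocyte, collecting duct and loop of Henle genes had medians below 0. The haemoglobin gene *Hbb-b1* stood at 839 (562–1115) in Dahl S and 136 (96.2–175) in SHR, and *Havcr1* at 7.64 (5.0–10.3) in Dahl S and 0.34 (0.116–0.564) in SHR. *Cyp8b1* (ENSRNOG00000019481, chromosome 8, 127018908 to 127020878), a sterol hydroxylase of bile acid synthesis, stood at 1.46 (0.68–2.23) in Dahl S and 43 (30.5–55.5) in SHR. *Ephx2*, the soluble epoxide hydrolase that degrades epoxides of arachidonic acid, stood at 3.02 (1.85–4.19) in Dahl S and 28.5 (20.9–36) in SHR, and *Alox15* (ENSRNOG00000019183, chromosome 10, 57185940 to 57194388) at 37.7 (26.7–48.6) in Dahl S and 4.07 (2.61–5.54) in SHR. *Dbp* was also lower in Dahl S than in SHR, at 41.9 (32.7–51.1), the same Dahl S value as above, against 208 (172–244).

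Of the 15 kidney injury genes 6 were at least 2-fold higher in Dahl S and none was 2-fold lower (median log2 ratio 0.59, percentile 100): *Havcr1*, *Spp1*, *Lcn2*, clusterin (*Clu*), *Fga* and *Fgb*. *Spp1* stood at 929 (618–1240.5) in Dahl S and 370.4 (254–487) in SHR and *Clu* at 173 (141–206) in Dahl S and 75.1 (61.8–88.4) in SHR. Of 6 red blood cell genes 4 were 2-fold higher (median log2 ratio 2.08, percentile 100; 1.297 with no minimum), among them *Hba2* at 3507 (1957–5056) in Dahl S and 802 (517–1087) in SHR, *Hbb* and *Hba-a2*. Haemoglobin took 1.67% of all FPKM in Dahl S and 0.363% in SHR, beside each list with a median above 0. All 11 macrophage and dendritic cell markers were above 0 (median log2 ratio 0.51, percentile 100), with limits apart for *Csf1r*, the receptor of macrophage colony-stimulating factor. T and B lymphocyte markers were above 0 in 10 of 11 (median log2 ratio 0.50, percentile 99.98; 0.26 with a pseudocount of 5). The T cell receptor chain gene *Cd3d* had 1.47 (0.358–2.57) in Dahl S and was listed at 0 in SHR, and *Cd3g* was 2-fold higher in Dahl S with overlapping limits. All 10 MHC class II genes were above 0 (median log2 ratio 0.37, percentile 99.9), with *RT1-Bb* 2-fold higher at 169 (118–219.9) in Dahl S and 49.95 (35.5–64.4) in SHR. Among class I genes, which had a median of 0.03 (percentile 73), *RT1-CE10* was higher in Dahl S, while *RT1-A1*, *RT1-CE1* and *RT1-O1* were higher in SHR, with *RT1-A1* at 129 (91.3–166) in Dahl S and 345 (217–473) in SHR and overlapping limits for *RT1-CE1* and *RT1-O1*. The copies of RT1 differ between strains and can share reads. Of 31 oxidative stress and glutathione genes 4 were 2-fold higher in Dahl S (median log2 ratio 0.15, percentile 99.6): *Gstm7*, *Gstm1*, *Sod3* and, with overlapping limits, *Gpx3*. Immediate early genes had a median of 0.19 (percentile 99.6), or 0.05 with a minimum mean of 5, and *Egr1* was 2-fold lower in Dahl S.

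Lower in Dahl S than in SHR were 4 of 9 adipocyte genes (median log2 ratio -0.76, percentile 0). *Ucp1*, the uncoupling protein of brown fat, stood at 37.7 (26.2–49.2) in Dahl S and 155 (107–203) in SHR, lipoprotein lipase (*Lpl*) at 21.2 (15.1–27.4) in Dahl S and 80.9 (54.4–107) in SHR, and *Cidea* and *Fabp4* were the other two. Collecting duct principal cell markers were below 0 in 10 of 11 (median log2 ratio -0.32, percentile 0.090), with the water channel *Aqp4* 2-fold lower at 11.5 (9.3–13.7) in Dahl S and 33.9 (28.8–39.1) in SHR. Intercalated cell markers (10 of 11 below 0; median log2 ratio -0.38, percentile 0) and loop of Henle markers (7 of 10; median log2 ratio -0.46, percentile 0) had medians below 0. Distal convoluted tubule markers (6 of 8; median log2 ratio -0.27, percentile 0.59) and endothelial markers (10 of 10; median log2 ratio -0.30, percentile 0.030) did too. None of their members was 2-fold apart. Their most abundant members included *Umod*, given above, and *Slc12a1*, the sodium-potassium-chloride cotransporter, at 299.9 (242–357) in Dahl S and 485 (366–604) in SHR. Proximal tubule markers went the other way, with 20 of 25 above 0 (median log2 ratio 0.38, percentile 100) and *Gatm*, of creatine synthesis, 2-fold higher at 241 (171–310.1) in Dahl S and 113 (80.1–145) in SHR. Of 12 clock genes 4 were 2-fold lower in Dahl S (*Dbp*, *Per3*, *Nr1d1* and *Tef*) and 2 were higher (*Arntl* and *Npas2*), with a median of -0.64 (percentile 0). Peroxisomal and fatty acid oxidation genes were below 0 in 16 of 23 (median log2 ratio -0.25, percentile 0), with the fatty acid sensor *Ppara* 2-fold lower at 4.2 (2.49–5.91) in Dahl S and 10.4 (7.13–13.7) in SHR. Among interferon-stimulated genes (median log2 ratio -0.04, percentile 37.6), *Ifit1* stood at 0.244 (0–0.552) in Dahl S and 7.72 (5.02–10.4) in SHR and *Mx2* at 7.95 (5.92–9.99) in Dahl S and 17.8 (13.6–22) in SHR.

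Further records named by ratio were, higher in Dahl S, *Ubd* at 21.5 (14.2–28.9) in Dahl S and 0.262 (0–0.634) in SHR, the olfactory receptor *Olr1668* at 36.5 (24.9–48) in Dahl S and 1.84 (0.851–2.83) in SHR, the histone gene *Hist1h2bc*, *Matn1*, *Megf11*, *Timd2* and *Zmynd15*. Lower in Dahl S were *Dear* at 0.729 (0–2.13) in Dahl S and 15.4 (10.02–20.8) in SHR, and the beta-defensin *Defb11* at 3.08 (0–6.16) in Dahl S and 15.9 (8.5–23.4) in SHR. So were the peroxisomal oxidase *Acox2*, at 10.7 (7.23–14.3) in Dahl S and 42.6 (30.1–55.1) in SHR, *Rdh2*, *Pdia5*, *Htr2b*, *Ppcdc* and *Eya3*. *Timd2*, *Zmynd15*, *Dear*, *Htr2b*, *Ppcdc* and *Eya3* share their loci with other records. Over all records 486 were higher and 419 lower, with limits apart for 243 and 222. The total of 905 became 1432 with a pseudocount of 0.1, 270 with 5 (132 higher and 138 lower), 1440 with no minimum, 361 with a minimum mean of 5 (170 higher and 191 lower) and 516 with the records of each locus summed.

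**Figure D3:**
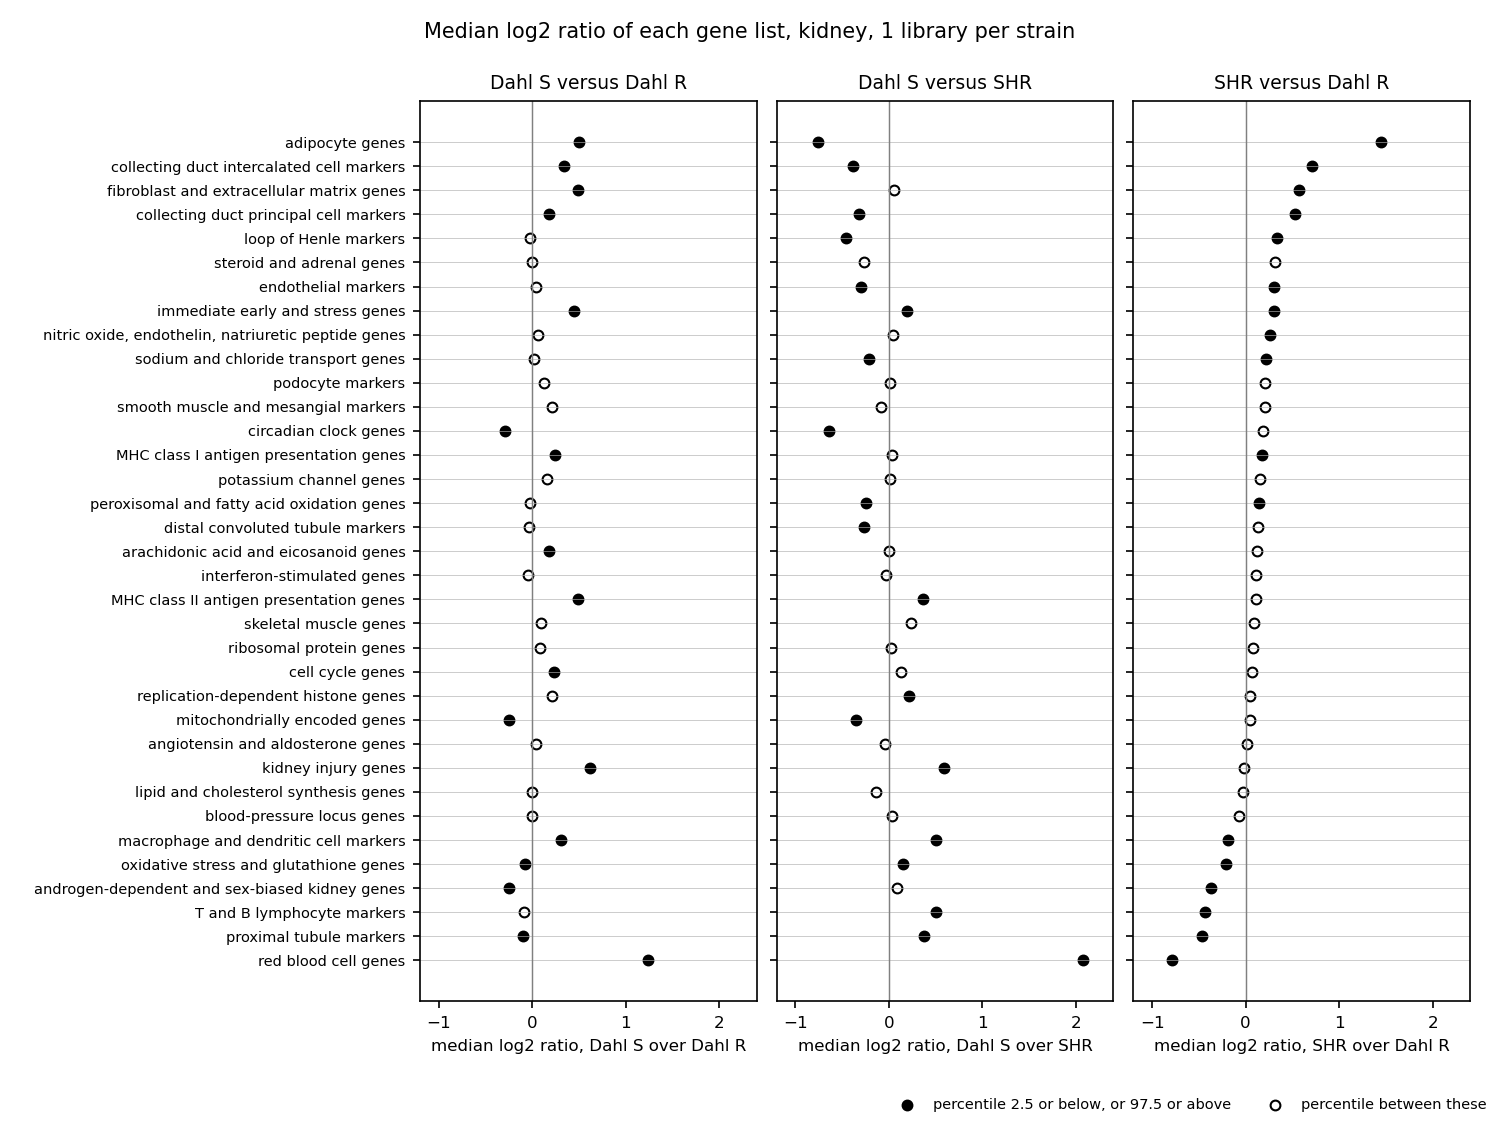
Median log2 ratio (horizontal axis) of the 35 gene lists with a percentile, in each of the 3 comparisons of kidney libraries; filled points have a percentile of at most 2.5 or at least 97.5 among 10000 random lists matched on size and expression. Adipocyte genes have the highest median in SHR over Dahl R (1.45) and red blood cell genes the lowest (-0.79).

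In SHR compared with Dahl R, a hypertensive against a salt-resistant strain, the lists of adipocyte, collecting duct and loop of Henle genes had medians above 0 in SHR, the proximal tubule list had a median below 0, and *Cyp2c23* and *Cyp1a1* were lower. *Ucp1* (ENSRNOG00000003580, chromosome 19, 26527548 to 26535621) stood at 155 (107–203) in SHR and 26.3 (18.2–34.4) in Dahl R, and *Scd1*, a fatty acid desaturase, at 64.2 (45.9–82.5) in SHR and 10.8 (8.36–13.3) in Dahl R. *Cyp8b1* stood at 43 (30.5–55.5) in SHR and 1.45 (0.735–2.16) in Dahl R and *Ephx2* (ENSRNOG00000017286, chromosome 15, 45497946 to 45556106) at 28.5 (20.9–36) in SHR and 1.91 (1.13–2.69) in Dahl R. On the lower side, *Cyp2c23*, the main epoxygenase of the rat kidney, stood at 127 (86.4–168) in SHR and 457 (278–636) in Dahl R, and *Cyp1a1* at 2.09 (1.26–2.92) in SHR and 25.1 (17.8–32.3) in Dahl R. Angiotensinogen (*Agt*) stood at 25.3 (17.9–32.6) in SHR and 60.4 (42.8–78) in Dahl R.

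Of 9 adipocyte genes all were above 0 and 6 were at least 2-fold higher in SHR (median log2 ratio 1.45, percentile 100): *Ucp1*, *Cidea*, *Lpl*, *Fabp4*, *Cfd* and *Lipe*. *Fabp4* stood at 148 (105–191) in SHR and 47.2 (32.5–61.9) in Dahl R and adiponectin (*Adipoq*) at 28.7 (20.3–37.2) in SHR and 14.2 (9.55–18.8) in Dahl R. Peroxisomal and fatty acid oxidation genes were above 0 in 16 of 23 (median log2 ratio 0.15, percentile 98.1; 0.08 after upper-quartile scaling), with *Pdk4*, an inhibitor of glucose oxidation, at 14.9 (10.2–19.5) in SHR and 4.9 (2.95–6.85) in Dahl R. Lipid and cholesterol synthesis genes had a median of -0.03 (percentile 16.9), with *Scd1* the only member 2-fold apart.

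All 11 intercalated cell markers were above 0 in SHR (median log2 ratio 0.71, percentile 100), and *Slc26a4*, the chloride-bicarbonate exchanger pendrin, was 2-fold higher at 36.8 (26–47.6) in SHR and 17 (12–22) in Dahl R. Principal cell markers were above 0 in 10 of 11 (median log2 ratio 0.53, percentile 100), with *Aqp4* 2-fold higher, and the epithelial sodium channel subunit *Scnn1b*, at 47.8 (36.4–59.1) in SHR and 27 (20.7–33.2) in Dahl R, had limits apart. Distal convoluted tubule markers were above 0 in 5 of 8 (median log2 ratio 0.13, percentile 87.6). Loop of Henle markers (8 of 10; median log2 ratio 0.34, percentile 99.98) and endothelial markers (10 of 10; median log2 ratio 0.31, percentile 99.95) were above 0 as lists. Sodium and chloride transport genes were above 0 in 19 of 29 (median log2 ratio 0.22, percentile 100), with *Slc26a4* the 1 member 2-fold apart. Fibroblast and matrix genes were above 0 in 11 of 14 (median log2 ratio 0.57, percentile 100), with *Lum* and *Postn* 2-fold higher, *Postn* at 4.12 (2.99–5.24) in SHR and 1.33 (0.67–1.99) in Dahl R. Immediate early genes were above 0 in 15 of 18 (median log2 ratio 0.30, percentile 99.98), with *Egr1* at 23.3 (16.5–29.97) in SHR and 4.84 (3.16–6.51) in Dahl R. Nitric oxide, endothelin and natriuretic peptide genes had a median of 0.26 (percentile 99.7), or 0.10 with no minimum, and no member 2-fold apart.

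Proximal tubule markers were below 0 in 24 of 25 (median log2 ratio -0.46, percentile 0). *Gatm* was 2-fold lower at 113 (80.1–145) in SHR and 241 (170.3–311) in Dahl R, and the carboxylate transporter *Slc13a3*, at 130.4 (94.8–166) in SHR and 259 (189–329) in Dahl R, had limits apart. In the arachidonic acid list (median log2 ratio 0.12, percentile 90.6) 3 of 20 were 2-fold lower, *Cyp2c23*, *Cyp2c11* and *Alox15*, and *Ephx2* was the 1 member 2-fold higher. Oxidative stress and glutathione genes were below 0 in 23 of 31 (median log2 ratio -0.21, percentile 0), with the NADPH oxidase gene *Cybb* 2-fold lower, and androgen-dependent genes in 9 of 12 (median log2 ratio -0.37, percentile 0.020), with *Cyp2c11* 2-fold lower. Macrophage and dendritic cell markers were below 0 in 9 of 11 (median log2 ratio -0.19, percentile 1.12). T and B lymphocyte markers were below 0 in 8 of 11 (median log2 ratio -0.43, percentile 0), with *Cd3e*, *Cd3d* and *Cd3g* 2-fold lower. These transcripts were scarce, with *Cd3e* at 0.785 (0.261–1.31) in SHR and 3.4 (1.81–4.99) in Dahl R, and the list median was 0.05 with a minimum mean of 5. Red blood cell genes had a median of -0.79 (percentile 0.020), or -0.51 with no minimum, and *Hbb-b1* was 2-fold lower. In the potassium channel list (median log2 ratio 0.16, percentile 89.6) *Kcnj15* was 2-fold lower at 19.7 (13.7–25.6) in SHR and 41.2 (29.2–53.2) in Dahl R. Among class I genes (median log2 ratio 0.18, percentile 99.1; 0.12 after upper-quartile scaling) *RT1-A1* and, with overlapping limits, *RT1-CE1* and *RT1-O1* were 2-fold higher, and *RT1-CE10* was 2-fold lower. MHC class II genes were above 0 in 6 of 10 (median log2 ratio 0.11, percentile 84).

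Other records named by ratio were *Defb11*, *Resp18*, *Cox8b*, *Acox2*, *Nupr1* and *Pdia5* on the higher side, with *Nupr1*, a stress-response protein, at 95.9 (68.2–124) in SHR and 24.1 (15.8–32.5) in Dahl R. On the lower side were *Olr1668* (ENSRNOG00000029622, chromosome 20, 92810 to 93748) at 1.84 (0.851–2.83) in SHR and 32.8 (22.7–43) in Dahl R and the carnosinase *Cndp1* at 14.6 (10.3–18.9) in SHR and 55.7 (39.3–72.1) in Dahl R. The sorting receptor *Sorcs2* stood at 3.48 (2.02–4.95) in SHR and 15.5 (11.6–19.5) in Dahl R, and the others were *Megf11*, *Hist1h2bc*, *Matn1*, *Ugt2b36*, *Ubd*, *Ces1e* and *Lass6*. Over all records 451 were higher and 336 lower in SHR, with limits apart for 254 and 210. The total of 787 became 1270 with a pseudocount of 0.1, 214 with 5, 1231 with no minimum, 320 with a minimum mean of 5 and 455 with the records of each locus summed.

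Genes of blood-pressure regulation were given by rule in every comparison. *Agt* stood at 52.2 (37.1–67.3) in Dahl S, 2-fold above SHR. The converting enzyme gene *Ace* stood at 4.95 (3.5–6.4) in Dahl S, 4.56 (3.04–6.08) in Dahl R and 3.74 (2.67–4.81) in SHR. The fatty acid transporter *Cd36* was read from a record named LOC100365047 and described as platelet glycoprotein 4, at a locus of 3 records. That record stood at 9.38 (7.16–11.6) in Dahl S, 8.87 (6.83–10.9) in Dahl R and 8.27 (6.34–10.2) in SHR. Reads of the records there cannot be separated, so equal levels of an intact *Cd36* transcript are not shown. *Rffl* stood at 7.0 (4.65–9.36) in Dahl S, 7.52 (5.07–9.97) in Dahl R and 8.02 (5.77–10.3) in SHR. The limits of *Cd36* and of *Rffl* overlapped in every pair. The angiotensin and aldosterone list had medians of 0.05, -0.05 and 0.02 in the order Dahl S over Dahl R, Dahl S over SHR and SHR over Dahl R (percentiles 60.3, 36.6 and 51.6). Between Dahl S and Dahl R its 1 member 2-fold apart was *Anpep*, higher in Dahl S with overlapping limits. Of 26 measured genes of blood-pressure loci none was 2-fold apart between Dahl S and Dahl R (median log2 ratio 0.00, percentile 28.3), with *Plcd1* the 1 member whose limits were apart. Against SHR, 4 were 2-fold higher and 2 lower in Dahl S (median log2 ratio 0.04, percentile 73.7), and in SHR over Dahl R 1 was higher and 3 lower (median log2 ratio -0.07, percentile 5.07). *Endog*, a mitochondrial nuclease, stood at 42.1 (29–55.3) in Dahl S, 42.8 (29.9–55.7) in Dahl R and 12.5 (8.14–16.8) in SHR, and *Sorcs2* at 14.6 (10.7–18.6) in Dahl S. Adamts16, Xist, Malat1, Meg3 and Neat1 were not matched to a record and are not analysed here.

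Each library held genes that stood apart from both others, at least 2-fold and in the same direction. There were 356 such records for Dahl S (201 above and 155 below), 239 for Dahl R (100 above and 139 below) and 341 for SHR (176 above and 165 below), with limits apart from both others for 130, 100 and 186 of them. *Havcr1*, *Zmynd15* and *Nfil3* were above in Dahl S, with *Dbp*, *Tef*, *Htr2b* and *F5* below. *Bcl6*, at 8.5 (5.74–11.3) in Dahl S, 37.5 (26.6–48.5) in Dahl R and 12.2 (8.61–15.8) in SHR, and *Cyp1a1* were above in Dahl R. *Cyp8b1*, *Ephx2*, *Ucp1*, *Lpl* and *Acox2* were above in SHR, with *Olr1668*, *Matn1*, *Megf11* and *Endog* below. The simulated error gave means of 67.6 above and 152 below for Dahl S, 65.1 and 93.1 for Dahl R, and 88.2 and 88.2 for SHR, so the records below in Dahl S were as many as that error gives (155 against 152). The total of 936 became 1564 with a pseudocount of 0.1, 233 with 5, 1593 with no minimum, 327 with a minimum mean of 5 and 416 with limits apart.

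Long non-coding records, the subject of the series, were measured in all 3 libraries: 1872 reached 1 FPKM in Dahl S, 1808 in Dahl R and 1811 in SHR. The most abundant was FQ220900 (chromosome 10, 40318802 to 40319382), at 13887 in Dahl S, 10805 in Dahl R and 7536 in SHR, with lower limits of 0. FQ213809, FQ220842, AY604720 and FQ224241, also among the most abundant, lie on the mitochondrial chromosome, and FQ224534 shares the locus of *Hbb*. As the use of strand is not given, reads of other genes there cannot be told from long non-coding RNA. Identifiers and positions are those of the files, whose genome build is not given. Of 2217 records with a mean of at least 0.5 FPKM, 90 were higher and 71 lower in Dahl S than in Dahl R, 108 higher and 87 lower in Dahl S than in SHR, and 90 higher and 73 lower in SHR than in Dahl R. The simulated error gave means of 40.6, 43.0 and 32.2. Limits were apart for 108, 145 and 126 of the totals of 161, 195 and 163. These include records listed at 0 with limits of 0 and 0, which are apart from any lower limit above 0. FQ226568, at 0 (0–0) in Dahl S and 2.17 (0.229–4.11) in SHR, is an example. Among records alone at their locus, FQ222763 (chromosome 17, 6294632 to 6294950) was higher in Dahl S, at 163 (113–212) in Dahl S, 60.1 (39.7–80.5) in Dahl R and 69.3 (47.1–91.5) in SHR. FQ210070 (chromosome 20, 5002207 to 5003423) was lower in SHR, at 29.6 (20.3–38.8) in Dahl S, 19.8 (13.5–26) in Dahl R and 2.58 (1.42–3.75) in SHR. So was BC086450 (chromosome 15, 57833871 to 57921109), at 12.2 (7.7–16.7) in Dahl S, 6.34 (3.83–8.86) in Dahl R and 1.33 (0.591–2.07) in SHR. DQ266361 (chromosome 4, 61726886 to 61727127) was higher in SHR than in Dahl R, at 19.1 (11–27.1) in SHR and 5.14 (1.81–8.48) in Dahl R. At a locus of 6 records *H19*, an imprinted long non-coding RNA, was 2-fold higher in SHR, at 0.655 (0.227–1.08) in Dahl S, 0.603 (0.235–0.971) in Dahl R and 2.58 (1.57–3.58) in SHR.

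Most long non-coding records that differed shared their locus with other records: 147 of 161, 166 of 195 and 140 of 163, against 63.6% of those measured. The ratios furthest from 0 came from such loci. FQ211801 (chromosome 1, 208429494 to 208430184) stood at 134 (88.9–179.6) in Dahl S and 168 (115–221) in Dahl R and was listed at 0 in SHR. FQ212892 (chromosome 2_random, 2921999 to 2929322) stood at 25.7 (17.4–34) in Dahl S, 1.1 (0.411–1.79) in Dahl R and 25.7 (18–33.4) in SHR. FQ212980 at the same locus was listed at 0 in Dahl S and SHR and stood at 19.2 (13–25.4) in Dahl R. The sum over the 9 records of that locus was 79.1 FPKM in Dahl S, 68.5 in Dahl R and 68.5 in SHR. Over 21 records of a locus on chromosome 16_random the sums were 588, 478 and 424. They include FQ231953, at 129 (92.1–167) in Dahl S and 11.7 (7.31–16) in Dahl R, and FQ218242, at 5.08 (0–192) in Dahl S and 83.7 (59.5–108) in Dahl R. XR_086281 (chromosome 6, 134099270 to 134149525) stood at 0.296 (0–0.735) in Dahl S, 0.0877 (0–0.212) in Dahl R and 8.06 (5.01–11.1) in SHR. With only records alone at their locus the totals became 14 (4 higher and 10 lower), 29 and 23. For SHR over Dahl R the split turned to 20 higher and 25 lower with a pseudocount of 5, and to 52 and 59 with a minimum mean of 2. With a pseudocount of 0.1 the totals became 340, 363 and 340.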

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

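With 1 library per strain no replicate could be left out, and no paired analysis was possible because each strain has a single library with no partner. Counts depended on the pseudocount and the minimum mean, since ratios of scarce transcripts are shrunk or removed by them. All counts below are in the order Dahl S with Dahl R, Dahl S with SHR and SHR with Dahl R. With a pseudocount of 0.1 the records at least 2-fold apart numbered 1196, 1432 and 1270, the long non-coding ones 340, 363 and 340, and those apart in 1 strain 1564. With a pseudocount of 5 they numbered 178, 270 and 214, then 47, 63 and 45, and 233. With no minimum they numbered 1264, 1440 and 1231, and 1593 apart in 1 strain, and Pearson's r was 0.980, 0.977 and 0.981. With a minimum mean of 5 they numbered 230, 361 and 320, and 327 apart in 1 strain. The median of T and B lymphocyte markers in SHR over Dahl R then changed sign, from -0.43 to 0.052, as only *Cd4*, at a locus of 24 records, *Ptprc* and *Igj* stayed in the list. Requiring limits apart gave 302, 465 and 464 records, and 416 apart in 1 strain. Chosen after seeing the data, summing the records of each locus gave 382, 516 and 455 records, and keeping only long non-coding records alone at their locus gave 14, 29 and 23, both by construction over fewer records. Leaving out the members of the red blood cell, adipocyte and clock lists, also chosen then, gave 715, 891 and 780. Median-of-ratios, upper-quartile and trimmed-total scaling, and leaving out records with a locus span under 300 bases, kept each of these counts within 1.5 times its main value. The number of list medians with an extreme percentile was 53, and 50 to 54 under the alternatives run for lists. Of 780 values of named genes under the other pseudocounts and scalings, 675 stayed within the error drawn from their limits, 105 moved and 0 changed sign. A pseudocount cannot change a sign, and no scaling shifted a library by more than 0.04 in log2. The lack of sign changes was therefore nearly fixed in advance and is no evidence of stability. Of 909 list medians 50 changed sign, and the largest main median among these was that of the lymphocyte markers. The alternative of summing rows of a gene was not run, since every row has its own identifier. The size rule itself restricts what can be called, since the pseudocount puts an exact 2-fold difference just under the threshold. Of 50 simulated 2-fold differences 20, 16 and 13 were called, and of 50 4-fold ones 46, 45 and 43. These rates do not measure the effect of depth.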

Other observations

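The tests of library scaling and of a lower proximal tubule share were chosen only after the results were seen, as were the sensitivity values named as added. The other tests were written before their results. The test of tubule share first used the lymphocyte list (median -0.43), and was moved to the macrophage list after the lymphocyte median turned to 0.052 with a minimum mean of 5. The test of Dahl S scaling replaced one on clock genes grouped by their observed direction.

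Several gene groups fixed beforehand lie outside the comparisons above. Cell cycle genes were above 0 in 15 of 19 for Dahl S over Dahl R (median log2 ratio 0.23, percentile 98.4), but the median was 0.05 with a minimum mean of 5. Podocyte markers had medians of 0.13, 0.01 and 0.21 in the order Dahl S over Dahl R, Dahl S over SHR and SHR over Dahl R, and smooth muscle and mesangial markers 0.21, -0.08 and 0.20, all with percentiles between 2.5 and 97.5. Ribosomal protein genes had 0.09, 0.02 and 0.08, with no member 2-fold apart. All 13 mitochondrially encoded genes were below 0 for Dahl S over Dahl R (median log2 ratio -0.25, percentile 0.050) and over SHR (median log2 ratio -0.35, percentile 0), none of them 2-fold apart. Replication-dependent histone genes had 0.21, 0.22 (percentile 98.3, and a median of 0.11 with a pseudocount of 5) and 0.05, with *Hist1h2bc* at 17.8 (10.2–25.5) in Dahl S, 9.96 (5.35–14.6) in Dahl R and 1.22 (0.168–2.27) in SHR. Skeletal muscle genes (5 measured) had 0.09, 0.24 and 0.09. Steroid and adrenal genes (3 measured) had 0.00, -0.26 and 0.31, and adrenal medulla and nerve genes (2 measured) 0.60, 0.50 and 0.11. Sex-linked genes are not reported here, as 1 of 13 was measured. Named long non-coding RNAs (6 measured) had 0.02, -0.01 and 0.30, with *Rmrp* 2-fold higher in Dahl S than in Dahl R with overlapping limits.

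Further comparisons of lists already described are given here, and the rest only in the figure of list medians. For SHR over Dahl R the medians were -0.02 for kidney injury genes and 0.19 for clock genes, that of fibroblast and matrix genes was 0.06 for Dahl S over SHR, and that of lymphocyte markers was -0.09 for Dahl S over Dahl R. *Mx2*, an antiviral protein, was 2-fold lower in Dahl S than in Dahl R, at 7.95 (5.92–9.99) in Dahl S and 26 (20.3–31.8) in Dahl R, within an interferon-stimulated list of median -0.05, and *Ifit1* was 2-fold higher in SHR than in Dahl R within a list of median 0.12. Class I genes were above 0 in 22 of 25 for Dahl S over Dahl R (median log2 ratio 0.24, percentile 99.98), with none 2-fold apart. Sodium and chloride transport genes were below 0 in 20 of 29 for Dahl S over SHR (median log2 ratio -0.22, percentile 0).

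For SHR over Dahl R the medians of adipocyte, collecting duct and loop of Henle genes lay above 0 and those of proximal tubule, macrophage and lymphocyte markers below 0, while MHC class I (0.18), MHC class II (0.11) and distal convoluted tubule (0.13) genes were not below 0. A shared scaling shift of the library is argued against, since the median log2 ratio of all measured protein-coding records was 0.035. Depth cannot be judged from this median, because FPKM is already divided by the mapped fragments. A lower proximal tubule share with all other cell types raised alike would put macrophage and dendritic cell markers above 0. They had a median of -0.19, against 0.71 for intercalated cells, so these lists were not raised alike in these libraries. The difference of 0.90 exceeds the larger SD of 0.29, which is a spread between genes, not animals. The rule was set after the medians were seen and no macrophage marker had limits apart, so this was no independent test. More adipose tissue in the SHR sample is a candidate explanation for the fat genes. Of measured adipocyte markers 11 of 11 were above 0 with a median of 1.12 (8 of the 17 listed are in a fixed list). The median was 1.21 over the 4 outside the fixed lists, *Adrb3*, *Otop1*, *Slc36a2* and *Pparg*. Of all 11, 9 reached 1 FPKM in all libraries, while *Otop1* and *Slc36a2* stood at 0.231 and 0.834 in Dahl R. The values outside the lists thus rest on few and scarce genes, and *Cidec* and *Pparg* stayed level at log2 ratios of 0.06 and 0.11. More medulla in the SHR sample may account for part of the rise in collecting duct and loop of Henle markers. Of the measured medulla markers 6 of 6 were above 0 with a median of 0.52, although *Cryab*, the most abundant, stayed level at a log2 ratio of 0.02. Markers of the cortex did not fall together, as more medulla alone would have them do. Proximal tubule markers had a median of -0.46, but podocyte markers 0.21 (8 of 10 above 0) and distal convoluted tubule markers 0.13 (5 of 8). The intercalated cell list, whose 1 member 2-fold apart was *Slc26a4*, rose more than the medulla markers, with a median of 0.71. Whether its members come from medulla was not tested, and strain and age also stay open, untested.

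Circadian clock genes stood apart in Dahl S, with *Dbp*, *Tef*, *Nr1d1* and *Per3* lower and *Nfil3* higher than in Dahl R. *Arntl* and *Npas2* were above 0 but under the 2-fold rule, which includes the pseudocount. A shared scaling shift of the Dahl S library is argued against: it would move all records alike, and the median log2 ratio of measured protein-coding records was 0.037. That median cannot speak on depth, which is already divided out of FPKM. Another point of the daily cycle is a candidate explanation that cannot be told apart from a strain difference, since further clock output genes had a median of -0.12 with 3 of 8 measured (5 of the 8 are in a fixed list), or -0.34 over the 2 measured outside the fixed lists, and sampling times are not given in the sources used here. All 3 measured ones, *Usp2*, *Wee1* and *Bhlhe40*, were below 0, and for Dahl S over SHR, which the test did not cover, they were too, with medians of -0.50 over the 3 and -0.60 over the 2. Strain and age stay open, untested.

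Long non-coding records that differed lay mostly at loci shared with other records. If reads had been divided differently between overlapping records, such loci should hold both directions: of those with at least 2 differing records, 52.8% did for Dahl S with Dahl R (95% Clopper-Pearson interval 35.5 to 69.6), 40.9% for Dahl S with SHR and 43.2% for SHR with Dahl R. The other records of the locus moved the opposite way at 56.7% of 97 loci (46.3 to 66.7), 52.4% and 55.2%. The rest of the locus moved at least 2-fold the opposite way at only 5 of 97, 5 of 105 and 4 of 87 loci. The intervals include an even split, but an even split is no sound reference. A locus can hold up to 12 differing records, and independent changes of many records would often go both ways. Opposite moves were counted however small. These tests therefore cannot tell a division of reads from strain differences in single transcripts. It may still apply at single loci, such as the one of FQ212892, where records went opposite ways and the sum stayed at 79.1, 68.5 and 68.5.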
